A study of Homo sapiens with 51 samples.

How the data were processed

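Fractionated human K562 cells, an established chronic myelogenous leukaemia line, were profiled by rRNA-depleted, strand-specific RNA sequencing in 51 libraries. Per the labels, cells were lysed with NP-40, the lysate was spun through a sucrose cushion, the top layer was taken as cytoplasm, and the washed pellet was taken as nuclei. Each of 13 genotypes has both labelled fractions with 2 replicates, except that R376C has 1 cytoplasmic-labelled library, because its replicate 2 was not analysed here. A guide set of 16 libraries holds CRISPR interference cells with guides against DDX3 (sgDDX3), CNOT1 (sgCNOT1) or NUP160 (sgNUP160) and a guide against Gal4, a yeast gene (sgGal4). A transgene set of 35 libraries holds cells with lentiviral wild-type DDX3 (WT) or the mutants G325E, R326H, R351W, R376C, R534S and T532M, in which endogenous DDX3 was knocked down, cells with sgDDX3 and no transgene, and uninfected cells. Placing the uninfected cells in the transgene set is an assumption, since the labels do not say in which experiment they were grown. The file names of the samples with sgDDX3 and no transgene carry the letters wt and no guide, and their labels were followed. The labels also do not say whether replicates come from separate cultures, so the p-values measure only the spread between these samples.

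Per the submitters' processing notes, reads were aligned with STAR 2.7.5a to GRCh38; the gene annotation is not given in the sources used here. The deposited files give the raw read count of each gene in the STAR layout, unstranded and for each strand, with no normalization by the authors. Of the 60664 gene identifiers, 60463 were matched to symbols in a name table, 58396 in GENCODE release 29 and 60652 in either. The count on the strand that the directional kit produces was used, and the opposite strand held 5.30% to 11.6% of the counts of both strands. Gene counts per library ranged from 2354960 to 10386000 in the cytoplasmic-labelled libraries (median 5239670) and from 3716160 to 21365000 in the nuclear-labelled ones (median 9322280). R376C nuclear-labelled replicate 2 is left aside in these ranges. Reads not assigned to a gene made up 58.4% to 74.0% and 25.1% to 73.2% of the reads of these libraries, and were left out. No replicate pair was a copy of the same counts, with a chi-square per degree of freedom of at least 2.04.

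Counts were analysed in R 4.3.3 with edgeR 4.0.16, by robust quasi-likelihood fits with a coefficient per genotype, TMM normalization, the default expression filter and Benjamini-Hochberg adjusted p under 0.05. Separate fits were made for each set and labelled fraction, and fits of both fractions of a set gave a ratio change, the change in log2 of the nuclear-labelled over the cytoplasmic-labelled level. Genes tested numbered 16091 (cytoplasmic-labelled), 14324 (nuclear-labelled) and 17858 (ratio) in the guide set and 17530, 14222 and 18972 in the transgene set, and the biological coefficients of variation were 0.152, 0.0811 and 0.126 and 0.0878, 0.233 and 0.189. Values given as A ± B are log2 fold changes with standard errors, taken as the absolute change over the square root of F. The comparisons were each knockdown against sgGal4, the cells without transgene against uninfected cells and against WT, each mutant against WT, and an F test for differences among the 6 mutants. A test of the sgGal4 nuclear-labelled against cytoplasmic-labelled libraries and the levels of the targeted genes checked the labels. These comparisons, the lists and the alternatives were chosen before the data were examined, except where the text says otherwise.

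Groups of genes were tested with camera of limma 3.58.1 on voom values at a preset correlation of 0.01, adjusted over all lists and comparisons of a family (261 tests in the guide set, 688 in the transgene set, 29 for the fractions), with the test at an estimated correlation beside it, design columns in alphabetical order with capitals first. The 29 lists covered cytosolic ribosomal proteins, translation factors, ATF4 and integrated stress response genes, the unfolded protein response, heat shock, erythroid, megakaryocyte, granulocyte and monocyte, lymphocyte, and fibroblast and epithelial genes, and replication-dependent histones. They also covered immediate early and AU-rich mRNAs, interferon and NF-kappaB responses, nuclear-retained long non-coding RNAs, mitochondrially encoded mRNAs, snoRNA host genes, ZNF zinc finger proteins, nucleoporins, the CCR4-NOT complex, mRNA export factors, cytoplasmic mRNA decay, and DEAD-box helicases. The remaining lists were nuclear-encoded oxidative phosphorylation, mitochondrial ribosomal proteins, cholesterol synthesis, mitosis, G1/S and replication, and the proteasome. In each list, the members called over all genes were counted, and again after adjusting over the list alone. Genes named singly are those with the largest rises and falls (up to 5 each, or 2 each for a mutant) among called protein-coding genes with a mean of at least 10 CPM over the libraries of both groups and no overlap between the libraries of the groups. The targeted genes, MALAT1 and NEAT1, up to 4 members of a list with the lowest p, and up to 10 genes called the same way in at least 4 mutants are named as well. A gene at 0 counts in a group is given as a bound against 3 counts over that group.

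Alternatives tried were DESeq2 1.42.0 size factors, the DESeq2 test, no expression filter, unstranded counts, a block for the replicate number, 1 fit of all libraries, and leaving out each library of a comparison in turn. R376C nuclear-labelled replicate 2 was found to differ in content from every other nuclear-labelled library, and a fit without it was chosen after seeing the data; list tests in that fit numbered 456. Multigene families that share reads, such as histones and HSPA1A with HSPA1B, have uncertain single-gene values, and DDX3X reads in transgene libraries can come from the gene or the transgene.

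The procedure was tested on simulated data with no genotype effect, to which 200 changed genes were added at the observed depth and spread. For sgDDX3, the edgeR test recovered 5 of 67 genes changed 1.5-fold, 29 of 67 changed 2-fold and 50 of 66 changed 4-fold in the cytoplasmic-labelled libraries, 30, 45 and 60 in the nuclear-labelled ones, and 3, 13 and 44 for the ratio, with 5, 14 and 2 false calls. For G325E against WT it recovered 16, 36 and 55 in the cytoplasmic-labelled libraries, 2, 12 and 49 in the nuclear-labelled ones (40, 50 and 59 without R376C nuclear-labelled replicate 2) and 0, 3 and 24 for the ratio (13, 29 and 44 without it). No recovered gene had the wrong sign.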

Results

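In the sgGal4 libraries, nuclear RNAs were low in the nuclear-labelled libraries and high in the cytoplasmic-labelled ones. MALAT1, a nuclear-retained long non-coding RNA, had 24747 ± 379.2 CPM (mean ± SD, n = 2) in the cytoplasmic-labelled and 1998 ± 381.8 in the nuclear-labelled libraries (-3.24 ± 0.19), and NEAT1, the scaffold of paraspeckles, changed by -3.91 ± 0.17. Of the nuclear-retained long non-coding RNAs, 10 of 11 over all genes (10 adjusted over the list alone, median -2.65, adjusted p = 4.1e-06) were lower in the nuclear-labelled libraries. For nuclear-retained RNAs, adjusted p = 0.11 with an estimated correlation. Cytosolic ribosomal protein mRNAs went the other way, 78 of 83 over all genes (79 adjusted over the list alone, median 2.55, adjusted p = 2.9e-41) higher, as did 48 of 50 over all genes (48 adjusted over the list alone, median 2.77, adjusted p = 2.0e-29) of the replication-dependent histones. For ribosomal protein genes and histones, adjusted p = 0.14 and 0.14 with an estimated correlation, in this order. Among other coding genes, 69 of 82 over all genes (69 adjusted over the list alone, median 1.69, adjusted p = 6.4e-17) of the nuclear-encoded oxidative phosphorylation list were higher in the nuclear-labelled libraries. For oxidative phosphorylation genes, adjusted p = 0.12 with an estimated correlation. So were 67 of 76 over all genes (67 adjusted over the list alone, median 1.62, adjusted p = 3.1e-17) of the mitochondrial ribosomal proteins and 28 of 33 over all genes (29 adjusted over the list alone, median 1.44, adjusted p = 9.0e-13) of the translation factors. For mitochondrial ribosomal protein genes and translation factors, adjusted p = 0.12 and 0.14 with an estimated correlation, in this order. The largest rises were H4C12 (3.75 ± 0.23) and H4C11 (3.40 ± 0.27), histone genes that share reads, and the largest falls were the olfactory receptor gene OR10D3 (-6.95 ± 0.58) and CDK5RAP3 (-4.93 ± 0.36).

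By edgeR, 11615 genes differed between the labelled fractions of the sgGal4 cells, 5295 higher and 6320 lower in the nuclear-labelled libraries, with a median change of -0.22 over all genes. Of 29 lists tested, 15 were called and 0 kept the call with an estimated correlation. MALAT1 ranged from 20729 to 34091 CPM over 25 cytoplasmic-labelled libraries and from 1665 to 3549 over 25 nuclear-labelled ones. The no-feature share is the part of reads in no counted gene feature, among those assigned, ambiguous or in no feature on the counted strand. It leaves out unmapped reads and reads at several places, and cannot tell intergenic from intronic reads. The exception in content is R376C nuclear-labelled replicate 2. Its no-feature share was 62.8%, against 5.14% to 10.5% in the other nuclear-labelled libraries and 50.4% to 69.2% in the cytoplasmic-labelled ones. Content thus runs against the labels in 50 of 51 libraries, and fractions are named below only as labelled. A ratio change above 0 means a nuclear-labelled over cytoplasmic-labelled ratio above that of the control, after scaling. It can come from a higher nuclear-labelled level or from a lower cytoplasmic-labelled level. The content of the nuclear-labelled libraries, but for that exception, is that of cytoplasm.

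**Figure D1:**
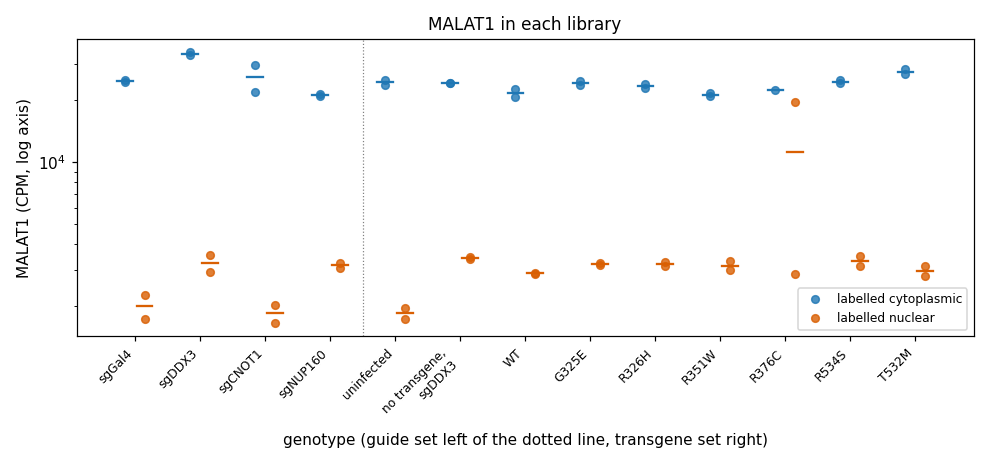
MALAT1 CPM in each library, on a log axis. Blue points are libraries labelled cytoplasmic, orange points are libraries labelled nuclear, and lines are group means.

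Each guide lowered its target in both labelled fractions of the guide set, also without any 1 library. DDX3X, which encodes a DEAD-box RNA helicase, was at 245 ± 16.9 CPM (mean ± SD, n = 2) in the sgGal4 cytoplasmic-labelled libraries and 59.3 ± 0.693 in the sgDDX3 ones, a change of -2.09 ± 0.17, and changed by -2.67 ± 0.09 in the nuclear-labelled ones. CNOT1, the scaffold of the CCR4-NOT deadenylase, changed by -4.53 ± 0.22 and -4.22 ± 0.08 with sgCNOT1, and NUP160, a nucleoporin of the Y complex, by -3.70 ± 0.22 and -3.38 ± 0.12 with sgNUP160. In the transgene set DDX3X was at 290 ± 0.790 CPM in uninfected, 130 ± 11.6 in no-transgene and 315 ± 2.11 in WT cytoplasmic-labelled libraries. In the nuclear-labelled libraries it was lower without transgene than in uninfected cells (-0.99 ± 0.20), a call lost without any 1 of these 4 libraries (-0.95 to -1.01). That fit holds R376C nuclear-labelled replicate 2, which widens its spread. DDX3X was at 272 ± 13.3 CPM in uninfected and 147 ± 0.685 in no-transgene nuclear-labelled libraries. Among the mutants, in the cytoplasmic-labelled libraries, it was higher than in WT in G325E (0.37 ± 0.09) and T532M (0.33 ± 0.09), calls lost without any 1 of 3 of the 4 libraries, and lower in R351W (-0.50 ± 0.09). R376C, with 1 library, had a higher value (0.40 ± 0.11, 428 CPM) that missed the threshold (adjusted p = 0.072). These reads can come from the gene or the transgene.

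**Figure D2:**
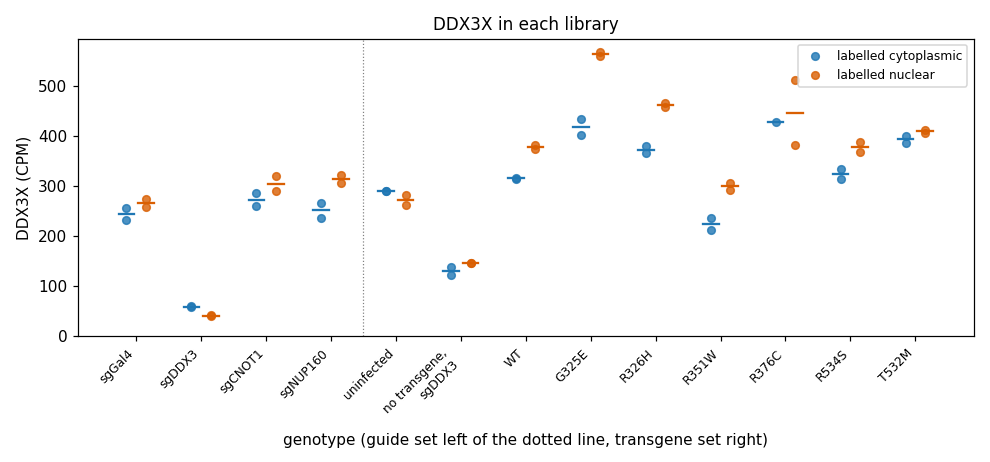
DDX3X CPM in each library, on a linear axis from 0. Blue points are libraries labelled cytoplasmic, orange points are libraries labelled nuclear, and lines are group means.

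With sgDDX3, cell cycle and ATF4 genes fell in the cytoplasmic-labelled libraries (n = 2 each). Of the mitosis list, 9 of 30 over all genes (24 adjusted over the list alone, median -0.73, adjusted p = 6.6e-18) fell, and of the replication-dependent histones, 12 of 45 over all genes (29 adjusted over the list alone, median -0.75, adjusted p = 2.0e-17). For mitosis genes and histones, adjusted p = 0.20 and 0.33 with an estimated correlation, in this order. G1/S and replication genes fell in 7 of 32 over all genes (23 adjusted over the list alone, median -0.57, adjusted p = 9.8e-16). For G1/S genes, adjusted p = 0.11 with an estimated correlation. Of the ATF4 and integrated stress response list, 9 of 31 over all genes (19 adjusted over the list alone, median -0.59, adjusted p = 1.4e-12) fell, among them SLC7A5, an amino acid transporter (-1.33 ± 0.16). For ATF4 list genes, adjusted p = 0.20 with an estimated correlation. The largest rise was IQCN (3.18 ± 0.33), and the largest falls were TBXA2R, the thromboxane receptor (-2.23 ± 0.21), and the Fc receptor gene FCGR2A (-2.20 ± 0.28). NF-kappaB response genes rose in 4 of 10 over all genes (4 adjusted over the list alone, median 0.86, adjusted p = 5.0e-04). For NF-kappaB genes, adjusted p = 0.20 with an estimated correlation.

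By edgeR 445 genes changed, 174 up and 271 down. The count fell to 37 without sgDDX3 replicate 1, 29 without sgDDX3 replicate 2, 44 without sgGal4 replicate 1 and 133 without sgGal4 replicate 2, all cytoplasmic-labelled.

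In the nuclear-labelled libraries, replication-dependent histones fell with sgDDX3 in 44 of 52 over all genes (45 adjusted over the list alone, median -1.09, adjusted p = 1.4e-41), such as H2BC11 (-1.65 ± 0.08) and H3C2 (-1.33 ± 0.06). For histones, adjusted p = 0.10 with an estimated correlation. Mitosis genes fell in 27 of 28 over all genes (27 adjusted over the list alone, median -0.72, adjusted p = 6.3e-18), with the proliferation marker MKI67 at -0.84 ± 0.08, and G1/S genes in 29 of 32 over all genes (29 adjusted over the list alone, median -0.63, adjusted p = 6.2e-18), with RRM2, a subunit of ribonucleotide reductase, at -1.25 ± 0.10. For mitosis genes and G1/S genes, adjusted p = 0.19 and 0.10 with an estimated correlation, in this order. ATF4 list genes fell in 20 of 31 over all genes (24 adjusted over the list alone, median -0.44, adjusted p = 1.1e-10), among them the one-carbon enzymes MTHFD2 (-0.86 ± 0.07) and SHMT2 (-0.83 ± 0.07), and proteasome genes in 26 of 36 over all genes (30 adjusted over the list alone, median -0.44, adjusted p = 2.8e-10). For genes of the ATF4 list and proteasome genes, adjusted p = 0.25 and 0.12 with an estimated correlation, in this order. NF-kappaB response genes rose in 6 of 11 over all genes (6 adjusted over the list alone, median 0.55, adjusted p = 0.0051), with NFKBIA, which encodes an inhibitor of NF-kappaB, at 0.80 ± 0.11 and RELB at 1.42 ± 0.22. For NF-kappaB genes, adjusted p = 0.26 with an estimated correlation. GPR153 rose by 2.73 ± 0.18, and TGM2, a transglutaminase (-2.15 ± 0.22), and FCGR2A (-1.70 ± 0.15) fell most. By edgeR 4480 genes changed, 2351 up and 2129 down, and 2892 without sgDDX3 nuclear-labelled replicate 2 or 2752 without sgGal4 nuclear-labelled replicate 1. In 1 fit of all libraries the count was 1465.

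The ratio of nuclear-labelled over cytoplasmic-labelled level rose with sgDDX3 for the growth factor binding protein gene IGFBP4 (2.49 ± 0.25), the mitochondrial isoleucyl-tRNA synthetase gene IARS2 (2.32 ± 0.26) and GALNT1, which starts O-glycosylation (2.31 ± 0.30). Of the unfolded protein response list, 4 of 17 over all genes (8 adjusted over the list alone, median 0.57, adjusted p = 1.6e-07) rose. For unfolded protein response genes, adjusted p = 0.33 with an estimated correlation. By edgeR the ratio rose for 407 genes and fell for 17, 424 together. The count was 262 without sgDDX3 cytoplasmic-labelled replicate 1, 201 without sgDDX3 nuclear-labelled replicate 2, 247 without sgGal4 cytoplasmic-labelled replicate 1 and 169 without sgGal4 nuclear-labelled replicate 2.

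With sgCNOT1, megakaryocyte, granulocyte and monocyte, and NF-kappaB genes rose and ribosomal protein and histone genes fell in the cytoplasmic-labelled libraries (n = 2 each). The largest rises were the adhesion receptor gene ADGRG1 (5.30 ± 0.46) and the integrin gene ITGAX (4.96 ± 0.26). Megakaryocyte genes rose in 6 of 6 over all genes (6 adjusted over the list alone, median 2.40, adjusted p = 7.3e-06), with the platelet glycoprotein gene GP1BA at 2.78 ± 0.29, and granulocyte and monocyte genes in 6 of 7 over all genes (6 adjusted over the list alone, median 1.20, adjusted p = 8.2e-05), with CSF3R at 1.07 ± 0.14. For megakaryocyte genes and granulocyte and monocyte genes, adjusted p = 0.20 and 0.13 with an estimated correlation, in this order. NF-kappaB response genes rose in 9 of 10 over all genes (9 adjusted over the list alone, median 1.48, adjusted p = 5.6e-07), with the adhesion molecule gene ICAM1 at 1.35 ± 0.18, and immediate early and AU-rich mRNAs in 15 of 32 over all genes (20 adjusted over the list alone, median 0.79, adjusted p = 1.2e-05). For NF-kappaB genes and immediate early and AU-rich mRNAs, adjusted p = 0.13 and 0.20 with an estimated correlation, in this order. Ribosomal protein genes fell in 60 of 83 over all genes (67 adjusted over the list alone, median -0.65, adjusted p = 7.1e-20), with RPLP0 at -1.11 ± 0.17, and histones in 37 of 45 over all genes (40 adjusted over the list alone, median -1.12, adjusted p = 1.3e-21). For ribosomal protein genes and histones, adjusted p = 0.39 and 0.31 with an estimated correlation, in this order. Falls were also called for G1/S genes in 27 of 32 over all genes (28 adjusted over the list alone, median -0.92, adjusted p = 4.8e-17) and snoRNA host genes in 10 of 20 over all genes (12 adjusted over the list alone, median -0.54, adjusted p = 1.2e-05). For G1/S genes and snoRNA host genes, adjusted p = 0.10 and 0.20 with an estimated correlation, in this order.

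By edgeR 3541 genes changed, 2091 up and 1450 down. The sgCNOT1 replicates 1 and 2 differed in content, with no-feature shares of 50.4% and 60.5%, MT-CO1 at 11669 and 4988 CPM, and a chi-square per degree of freedom of 27.6, against 13.01 or less in other pairs except R376C nuclear-labelled. The count rose to 6652 without sgCNOT1 replicate 1 and fell to 1360 without sgGal4 replicate 1 and 1823 without sgGal4 replicate 2, all cytoplasmic-labelled.

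In the nuclear-labelled libraries, snoRNA host genes fell with sgCNOT1 in 20 of 20 over all genes (20 adjusted over the list alone, median -1.41, adjusted p = 8.3e-13), with SNHG1 at -2.59 ± 0.10 and GAS5 at -1.38 ± 0.07. For snoRNA host genes, adjusted p = 0.10 with an estimated correlation. Histones fell in 50 of 52 over all genes (50 adjusted over the list alone, median -1.77, adjusted p = 1.5e-37) and ribosomal protein genes in 78 of 82 over all genes (78 adjusted over the list alone, median -0.73, adjusted p = 2.9e-38). For histones and ribosomal protein genes, adjusted p = 0.10 and 0.10 with an estimated correlation, in this order. Falls were also called for ZNF zinc finger genes in 206 of 412 over all genes (208 adjusted over the list alone, median -0.54, adjusted p = 5.5e-09) and oxidative phosphorylation genes in 50 of 78 over all genes (53 adjusted over the list alone, median -0.53, adjusted p = 6.1e-11). For ZNF genes and oxidative phosphorylation genes, adjusted p = 0.10 and 0.16 with an estimated correlation, in this order. The largest rises were ANXA1, an annexin (6.55 ± 0.38), and LGALS12, a galectin (5.14 ± 0.36). Interferon response genes rose in 15 of 18 over all genes (15 adjusted over the list alone, median 0.87, adjusted p = 2.2e-04), with IFIT3 at 1.85 ± 0.31, and NF-kappaB genes in 11 of 11 over all genes (11 adjusted over the list alone, median 1.41, adjusted p = 4.6e-06). For interferon genes and NF-kappaB genes, adjusted p = 0.17 and 0.13 with an estimated correlation, in this order. Rises were also called for megakaryocyte genes in 6 of 7 over all genes (6 adjusted over the list alone, median 2.79, adjusted p = 0.0014) and unfolded protein response genes in 11 of 17 over all genes (12 adjusted over the list alone, median 0.39, adjusted p = 7.4e-05), with the chaperone gene HSPA5 at 1.55 ± 0.08. For megakaryocyte genes and unfolded protein response genes, adjusted p = 0.20 and 0.16 with an estimated correlation, in this order. By edgeR 7110 genes changed, 3796 up and 3314 down, and 3966 in 1 fit of all libraries.

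The ratio fell with sgCNOT1 for snoRNA host genes, 7 of 20 over all genes (14 adjusted over the list alone, median -0.81, adjusted p = 4.9e-10), with SNHG1 at -1.58 ± 0.21, and for the collagen gene COL9A2 (-2.40 ± 0.33). For snoRNA host genes, adjusted p = 0.14 with an estimated correlation. It rose for MMUT, the mitochondrial methylmalonyl-CoA mutase gene (2.13 ± 0.29), and TWF1, an actin-binding protein gene (1.89 ± 0.33). Mitosis genes rose in 4 of 30 over all genes (14 adjusted over the list alone, median 0.51, adjusted p = 3.4e-09) and nucleoporins in 4 of 30 over all genes (10 adjusted over the list alone, median 0.41, adjusted p = 2.1e-07). For mitosis genes and nucleoporins, adjusted p = 0.29 and 0.33 with an estimated correlation, in this order. By edgeR the ratio changed for 1042 genes, 463 up and 579 down. The count was 3901 without sgCNOT1 cytoplasmic-labelled replicate 1, 486 without cytoplasmic-labelled replicate 2 and 229 without nuclear-labelled replicate 2 of sgCNOT1, and 281 without sgGal4 cytoplasmic-labelled replicate 1, 403 without nuclear-labelled replicate 1 and 480 without nuclear-labelled replicate 2. It was 446 in 1 fit of all libraries.

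With sgNUP160, ATF4 list genes fell in the cytoplasmic-labelled libraries (n = 2 each) in 24 of 31 over all genes (26 adjusted over the list alone, median -0.97, adjusted p = 6.2e-18), among them TRIB3, a pseudokinase gene (-1.86 ± 0.17), and PCK2, a mitochondrial gluconeogenic enzyme gene (-1.46 ± 0.16). For the list of ATF4 genes, adjusted p = 0.17 with an estimated correlation. Unfolded protein response genes fell in 11 of 17 over all genes (13 adjusted over the list alone, median -0.78, adjusted p = 3.0e-09), with XBP1 at -1.39 ± 0.19. For unfolded protein response genes, adjusted p = 0.33 with an estimated correlation. Mitochondrially encoded mRNAs fell in 13 of 13 over all genes (13 adjusted over the list alone, median -1.5005, adjusted p = 5.6e-10). For mitochondrially encoded mRNAs, adjusted p = 0.38 with an estimated correlation. The same direction held for ribosomal protein genes in 32 of 83 over all genes (53 adjusted over the list alone, median -0.53, adjusted p = 5.0e-13) and histones in 28 of 45 over all genes (30 adjusted over the list alone, median -0.88, adjusted p = 5.4e-12). For ribosomal protein genes and histones, adjusted p = 0.48 and 0.43 with an estimated correlation, in this order. Nuclear-encoded oxidative phosphorylation genes fell in 24 of 79 over all genes (31 adjusted over the list alone, median -0.49, adjusted p = 4.3e-08), mitochondrial ribosomal proteins in 12 of 76 over all genes (14 adjusted over the list alone, median -0.37, adjusted p = 2.1e-05) and proteasome genes in 4 of 35 over all genes (5 adjusted over the list alone, median -0.38, adjusted p = 3.7e-04). For oxidative phosphorylation genes, mitochondrial ribosomal protein genes and proteasome genes, adjusted p = 0.33, 0.29 and 0.48 with an estimated correlation, in this order. These libraries differed in content from the sgGal4 ones, with a no-feature share of 67.8% against 53.6%, ACTB at 475.8 against 1029.9 CPM and GAPDH at 190.2 against 325.99. OR5AU1, an olfactory receptor gene with 0 counts in sgGal4, rose at least 104.1-fold, COL12A1, a collagen gene, rose 108.3-fold (36.3 to 531.6 by counting, 139 against 3 counts), and NPC1L1, a cholesterol transporter gene, rose by 5.98 ± 0.52 on the log2 scale. The protease gene PRSS8 (-2.59 ± 0.23) and TES (-2.54 ± 0.31) fell most.

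By edgeR 2442 genes changed, 1134 up and 1308 down. The count fell to 382 without sgGal4 replicate 1, 1106 without sgGal4 replicate 2, 614 without sgNUP160 replicate 1 and 221 without sgNUP160 replicate 2, all cytoplasmic-labelled.

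In the nuclear-labelled libraries, histones fell with sgNUP160 in 43 of 52 over all genes (46 adjusted over the list alone, median -0.92, adjusted p = 5.8e-57) and ATF4 list genes in 26 of 31 over all genes (27 adjusted over the list alone, median -0.73, adjusted p = 1.7e-29). For histones and the ATF4 list, adjusted p = 0.10 and 0.12 with an estimated correlation, in this order. G1/S genes fell in 23 of 32 over all genes (25 adjusted over the list alone, median -0.46, adjusted p = 7.8e-18), with the licensing factor gene CDT1 at -0.79 ± 0.07. For G1/S genes, adjusted p = 0.10 with an estimated correlation. Heat shock genes rose in 11 of 14 over all genes (13 adjusted over the list alone, median 0.63, adjusted p = 5.4e-13) and erythroid genes in 15 of 27 over all genes (15 adjusted over the list alone, median 0.51, adjusted p = 7.5e-09), with the transferrin receptor gene TFRC at 0.79 ± 0.07 and the glycophorin gene GYPB at 0.82 ± 0.11. For heat shock genes and erythroid genes, adjusted p = 0.13 and 0.26 with an estimated correlation, in this order. TENT5C, a poly(A) polymerase gene (1.99 ± 0.12), and ADD2, an adducin gene (1.84 ± 0.21), rose most, and AKNA (-2.64 ± 0.13) and TRIB3 (-2.07 ± 0.10) fell most. By edgeR 2277 genes changed, 1054 up and 1223 down. The count was 955 without sgGal4 replicate 1, 1202 without sgGal4 replicate 2, 1016 without sgNUP160 replicate 1 and 1157 without sgNUP160 replicate 2, all nuclear-labelled, and 420 in 1 fit of all libraries.

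The ratio rose with sgNUP160 for ribosomal protein mRNAs, 43 of 83 over all genes (60 adjusted over the list alone, median 0.80, adjusted p = 1.7e-30), and for oxidative phosphorylation genes, 14 of 82 over all genes (32 adjusted over the list alone, median 0.45, adjusted p = 1.7e-06), with the cytochrome oxidase gene COX5B at 1.45 ± 0.22. For ribosomal protein genes and oxidative phosphorylation genes, adjusted p = 0.21 and 0.31 with an estimated correlation, in this order. Mitosis genes rose in 6 of 30 over all genes (16 adjusted over the list alone, median 0.61, adjusted p = 9.5e-10), with the spindle gene ASPM at 1.82 ± 0.28. For mitosis genes, adjusted p = 0.23 with an estimated correlation. Rises were also called for unfolded protein response genes in 9 of 17 over all genes (12 adjusted over the list alone, median 0.90, adjusted p = 5.8e-09) and mitochondrially encoded mRNAs in 3 of 13 over all genes (12 adjusted over the list alone, median 1.91, adjusted p = 1.3e-19). For unfolded protein response genes and mitochondrially encoded mRNAs, adjusted p = 0.28 and 0.17 with an estimated correlation, in this order. By edgeR the ratio changed for 653 genes, 580 up and 73 down, with a median of 0.13 over all genes. Under DESeq2 size factors that median was -0.01 and 316 rose and 121 fell, and the DESeq2 test gave 528 and 239. The count was 196 without sgGal4 cytoplasmic-labelled replicate 1, 112 without sgGal4 nuclear-labelled replicate 2, 146 without sgNUP160 cytoplasmic-labelled replicate 2 and 103 without sgNUP160 nuclear-labelled replicate 1, and 403 in 1 fit of all libraries. Over the guide set, 129 of 261 list tests were called and 0 kept the call with an estimated correlation.

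**Figure D3:**
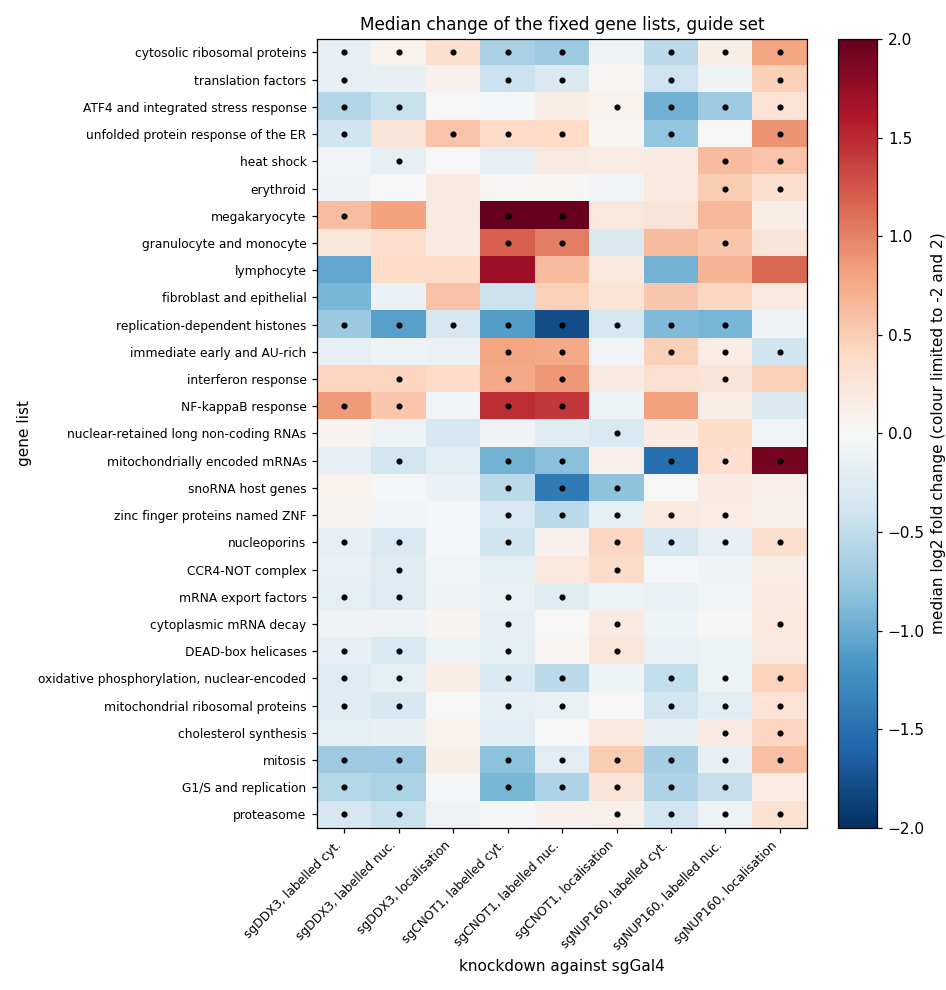
Median log2 fold change of each of 29 gene lists in the guide-set comparisons with sgGal4, by labelled fraction and for the ratio of nuclear-labelled over cytoplasmic-labelled. Colours are limited to -2 and 2, and dots mark lists with a camera adjusted p under 0.05 at the preset correlation.

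Without a transgene, sgDDX3 cells had lower ATF4 list genes than uninfected cells in the cytoplasmic-labelled libraries (n = 2 each), 27 of 30 over all genes (28 adjusted over the list alone, median -1.83, adjusted p = 9.4e-42). For ATF4 list genes, adjusted p = 0.0019 with an estimated correlation. SLC7A11, the cystine transporter gene (-3.09 ± 0.14), and PHGDH, which starts serine synthesis (-2.89 ± 0.13), were among them, and ASS1, an enzyme of arginine synthesis (-4.03 ± 0.26), and TF, which encodes transferrin (-3.60 ± 0.27), fell most. snoRNA host genes rose in 14 of 20 over all genes (15 adjusted over the list alone, median 0.64, adjusted p = 4.1e-12), with SNHG12 at 1.91 ± 0.13, and heat shock genes in 12 of 14 over all genes (13 adjusted over the list alone, median 0.79, adjusted p = 4.8e-10), with HSPA8 at 1.11 ± 0.10. For snoRNA host genes and heat shock genes, adjusted p = 0.032 and 0.27 with an estimated correlation, in this order. STXBP6 (2.52 ± 0.21) and THBS1, a thrombospondin gene (2.44 ± 0.21), rose most. By edgeR 4520 genes changed, 2450 up and 2070 down. The count was 2991 without uninfected cytoplasmic-labelled replicate 1 and 1823 in 1 fit of all libraries.

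The nuclear-labelled libraries gave 1015 genes, 489 up and 526 down, and 128 and 155 without uninfected replicates 1 and 2 and 124 and 123 without no-transgene replicates 1 and 2. R376C nuclear-labelled replicate 2 widens the spread of this fit, and in a reduced fit without it, chosen after seeing the data, 5699 changed, 2877 up and 2822 down. In that fit the ATF4 list fell in 30 of 30 over all genes (30 adjusted over the list alone, median -2.04, adjusted p = 3.1e-57), with the stress gene DDIT4 at -3.47 ± 0.08. For genes of the ATF4 list, adjusted p = 1.4e-04 with an estimated correlation. Heat shock genes rose in 13 of 14 over all genes (13 adjusted over the list alone, median 0.85, adjusted p = 1.7e-14), with HSPH1 at 1.26 ± 0.06, and histones fell in 42 of 50 over all genes (43 adjusted over the list alone, median -0.81, adjusted p = 1.9e-34). For heat shock genes and histones, adjusted p = 0.0050 and 0.079 with an estimated correlation, in this order. NEFH, a neurofilament gene (2.20 ± 0.07), rose most and CHAC1, a glutathione-degrading enzyme gene (-4.53 ± 0.30), fell most.

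The ratio changed for 60 genes, 39 up and 21 down, and for 0, 3, 0 and 6 without uninfected cytoplasmic-labelled replicates 1 and 2 and nuclear-labelled replicates 1 and 2, and for 370, 0, 3 and 3 without those of the no-transgene cells in the same order. In the reduced fit it was 2000, 1009 up and 991 down. There the ratio fell for ribosomal protein mRNAs in 47 of 82 over all genes (57 adjusted over the list alone, median -0.43, adjusted p = 8.0e-38), for immediate early and AU-rich mRNAs in 9 of 35 over all genes (17 adjusted over the list alone, median -0.55, adjusted p = 1.0e-08) and for snoRNA host genes in 10 of 20 over all genes (12 adjusted over the list alone, median -0.54, adjusted p = 2.0e-09), and rose for the scaffold gene IQGAP1 (1.45 ± 0.16) and the spectrin gene SPTAN1 (1.32 ± 0.12). For ribosomal protein genes, immediate early and AU-rich mRNAs and snoRNA host genes, adjusted p = 0.029, 0.011 and 0.013 with an estimated correlation, in this order.

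Against WT, the cells without transgene had lower ATF4 list genes in the cytoplasmic-labelled libraries (n = 2 each), 26 of 30 over all genes (29 adjusted over the list alone, median -1.58, adjusted p = 1.1e-65), with PHGDH at -2.77 ± 0.13 and SLC7A11 at -2.65 ± 0.14. For the list of ATF4 genes, adjusted p = 4.4e-04 with an estimated correlation. Heat shock genes rose in 10 of 14 over all genes (13 adjusted over the list alone, median 0.84, adjusted p = 1.9e-18), with HSPA8 at 1.29 ± 0.10, translation factors in 14 of 33 over all genes (19 adjusted over the list alone, median 0.33, adjusted p = 5.0e-11), with the helicase gene EIF4A2 at 0.64 ± 0.09, and snoRNA host genes in 8 of 20 over all genes (12 adjusted over the list alone, median 0.31, adjusted p = 5.4e-11). For heat shock genes, translation factors and snoRNA host genes, adjusted p = 0.14, 0.12 and 0.038 with an estimated correlation, in this order. ASS1 (-3.55 ± 0.26) and TF (-3.21 ± 0.27) fell most. By edgeR 1472 genes changed, 737 up and 735 down. The count was 681 and 480 without WT replicates 1 and 2 and 2565 without no-transgene replicate 1, all cytoplasmic-labelled, and 220 in 1 fit of all libraries.

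The nuclear-labelled libraries gave 60 genes against WT, 5 up and 55 down, 18 and 20 without WT replicates 1 and 2 and 6 and 7 without no-transgene replicates 1 and 2, and the DESeq2 test 129 up and 160 down. In the reduced fit they gave 2623, 1348 up and 1275 down, and the ATF4 list fell in 30 of 30 over all genes (30 adjusted over the list alone, median -1.48, adjusted p = 4.0e-89). For the ATF4 list, adjusted p = 2.8e-05 with an estimated correlation. Mitochondrially encoded mRNAs rose in 12 of 13 over all genes (13 adjusted over the list alone, median 0.83, adjusted p = 2.2e-28) and heat shock genes in 9 of 14 over all genes (11 adjusted over the list alone, median 0.33, adjusted p = 3.7e-08). For mitochondrially encoded mRNAs and heat shock genes, adjusted p = 0.047 and 0.021 with an estimated correlation, in this order. The mitochondrial rise holds against WT and not against uninfected cells, and MT-CO1 was at 4156 CPM in WT, 8005 in no-transgene and 12747 in uninfected nuclear-labelled libraries. Against uninfected cells the level of these mRNAs fell in 4 of 13 over all genes (5 adjusted over the list alone, median -0.39, adjusted p = 5.5e-05) and their ratio in 2 of 13 over all genes (13 adjusted over the list alone, median -1.19, adjusted p = 5.9e-14). For mitochondrially encoded mRNAs, adjusted p = 0.37 and 0.096 with an estimated correlation, in this order. The ratio changed for 0 genes by edgeR (702 at unadjusted p under 0.05; 18 by DESeq2), and for 502 in the reduced fit, 83 up and 419 down. There translation factors fell in 16 of 33 over all genes (22 adjusted over the list alone, median -0.41, adjusted p = 8.4e-24) and ribosomal protein mRNAs in 37 of 82 over all genes (56 adjusted over the list alone, median -0.41, adjusted p = 6.3e-40). For translation factors and ribosomal protein genes, adjusted p = 0.0012 and 0.024 with an estimated correlation, in this order. Lower ratios were also called for proteasome genes in 9 of 36 over all genes (21 adjusted over the list alone, median -0.39, adjusted p = 9.3e-13) and G1/S genes in 7 of 32 over all genes (15 adjusted over the list alone, median -0.31, adjusted p = 3.9e-11). For proteasome genes and G1/S genes, adjusted p = 0.013 and 0.0090 with an estimated correlation, in this order.

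In each mutant, ATF4 list genes were lower than in WT in the cytoplasmic-labelled libraries (n = 2 each, 1 for R376C, whose p-values take their spread from the other groups). They fell in 27 of 30 over all genes (30 adjusted over the list alone, median -1.73, adjusted p = 1.5e-77) in G325E and 29 of 30 over all genes (30 adjusted over the list alone, median -1.80, adjusted p = 3.2e-82) in R326H. For ATF4 list genes, adjusted p = 4.4e-04 and 4.4e-04 with an estimated correlation, in this order. They further fell in 28 of 30 over all genes (30 adjusted over the list alone, median -1.75, adjusted p = 2.7e-77) in R351W and 19 of 30 over all genes (28 adjusted over the list alone, median -0.98, adjusted p = 2.5e-71) in R376C. For genes of the ATF4 list, adjusted p = 4.4e-04 and 4.4e-04 with an estimated correlation, in this order. They further fell in 26 of 30 over all genes (30 adjusted over the list alone, median -1.63, adjusted p = 5.8e-70) in R534S and 27 of 30 over all genes (28 adjusted over the list alone, median -1.81, adjusted p = 5.1e-54) in T532M. For the list of ATF4 genes, adjusted p = 4.4e-04 and 7.2e-04 with an estimated correlation, in this order. TF stood at -3.63 ± 0.28 in G325E, -4.01 ± 0.29 in R351W and -2.80 ± 0.34 in R376C, while the asparagine synthetase gene ASNS stood at -3.41 ± 0.32 in R326H and -3.56 ± 0.31 in R534S. Heat shock genes rose in 9 of 14 over all genes (10 adjusted over the list alone, median 0.57, adjusted p = 5.8e-13) in G325E and 9 of 14 over all genes (11 adjusted over the list alone, median 0.74, adjusted p = 4.1e-19) in R534S, with HSPA8 at 1.23 ± 0.10 in R326H. For heat shock genes, adjusted p = 0.22 and 0.14 with an estimated correlation, in this order.

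By edgeR, genes changed up and down in the cytoplasmic-labelled libraries numbered 387 and 691 in G325E, 335 and 582 in R326H, 385 and 606 in R351W, 17 and 128 in R376C, 546 and 749 in R534S and 1198 and 1381 in T532M. Without replicates 1 and 2 of the mutant and then of WT, the totals were 450, 501, 464 and 455 for G325E (1078 with all), 523, 466, 399 and 416 for R326H (917), 453, 430, 406 and 468 for R351W (991), 465, 598, 588 and 508 for R534S (1295) and 1183, 1634, 1422 and 1291 for T532M (2579). For R376C they were 86 and 95 without WT replicates 1 and 2 (145 with all). In 1 fit of all libraries the totals were 183, 191, 184, 29, 240 and 802, from G325E to T532M.

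**Figure D4:**
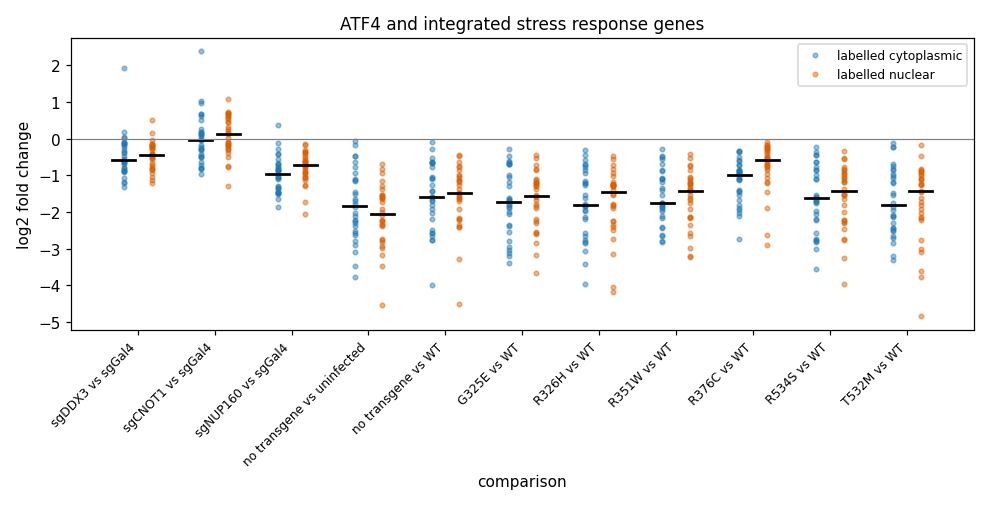
Log2 fold change of each gene of the ATF4 and integrated stress response list in each comparison, with lines at the medians. Transgene-set values for libraries labelled nuclear leave out R376C nuclear-labelled replicate 2.

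By edgeR in the cytoplasmic-labelled libraries, T532M had the most called genes of the mutants. SNPH, a syntaphilin gene (3.46 ± 0.31), rose most, and the zinc finger genes ZNF521 (-4.89 ± 0.23) and ZNF608 (-4.54 ± 0.31) fell most. Granulocyte and monocyte genes fell in 3 of 6 over all genes (3 adjusted over the list alone, median -0.77, adjusted p = 3.8e-04), with CSF3R at -1.48 ± 0.12 and ITGAM at -1.89 ± 0.21, and megakaryocyte genes rose in 3 of 6 over all genes (3 adjusted over the list alone, median 1.21, adjusted p = 0.0026). For granulocyte and monocyte genes and megakaryocyte genes, adjusted p = 0.19 and 0.14 with an estimated correlation, in this order. Histones fell in 21 of 50 over all genes (23 adjusted over the list alone, median -0.40, adjusted p = 4.0e-09). For histones, adjusted p = 0.24 with an estimated correlation. The F test among the 6 mutants called 851 genes in the cytoplasmic-labelled libraries, and fewer without either T532M replicate. Among the 5 mutants other than T532M it called 24 there, a test chosen after seeing the data. In the nuclear-labelled libraries, without R376C replicate 2 and thus with 1 R376C library, the same test called many more genes. The 24 thus does not show that these mutants are alike.

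In the nuclear-labelled libraries, genes up and down against WT numbered 4 and 51 in G325E, 7 and 52 in R326H, 0 and 45 in R351W, 0 and 8 in R376C, 13 and 55 in R534S and 468 and 349 in T532M. The DESeq2 test gave 102 and 154, 120 and 172, 83 and 147, 1427 and 353 and 177 and 183 in the first 5. Without replicates 1 and 2 of the mutant and then of WT, the totals were 15, 17, 19 and 19 for G325E, 13, 16, 19 and 19 for R326H, 15, 14, 18 and 18 for R351W, 12261, 402, 1 and 1 for R376C, 12, 8, 16 and 19 for R534S and 292, 141, 121 and 145 for T532M. The F test among mutants called 208, and without replicate 1 and without replicate 2 of each mutant 77 and 78 (G325E), 76 and 71 (R326H), 79 and 75 (R351W), 12667 and 3864 (R376C), 77 and 77 (R534S), 39 and 26 (T532M).

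The mutants gave in the reduced fit 2520, 2581, 2195, 402, 2977 and 5126 genes in the order G325E, R326H, R351W, R376C, R534S and T532M, with 3864 among mutants. ATF4 list genes fell in 30 of 30 over all genes (30 adjusted over the list alone, median -1.56, adjusted p = 7.6e-96) in G325E and 30 of 30 over all genes (30 adjusted over the list alone, median -1.46, adjusted p = 2.2e-95) in R326H. For the ATF4 list, adjusted p = 2.8e-05 and 2.8e-05 with an estimated correlation, in this order. The list fell in 30 of 30 over all genes (30 adjusted over the list alone, median -1.42, adjusted p = 2.5e-101) in R351W and 22 of 30 over all genes (25 adjusted over the list alone, median -0.58, adjusted p = 1.2e-62) in R376C. For ATF4 list genes, adjusted p = 2.8e-05 and 5.5e-05 with an estimated correlation, in this order. The list fell in 30 of 30 over all genes (30 adjusted over the list alone, median -1.44, adjusted p = 4.5e-81) in R534S and 29 of 30 over all genes (30 adjusted over the list alone, median -1.43, adjusted p = 3.1e-47) in T532M. For genes of the ATF4 list, adjusted p = 3.6e-05 and 1.5e-04 with an estimated correlation, in this order. Mitochondrially encoded mRNAs rose in 12 of 13 over all genes (12 adjusted over the list alone, median 1.02, adjusted p = 1.1e-28) in R534S and 13 of 13 over all genes (13 adjusted over the list alone, median 1.39, adjusted p = 4.2e-30) in T532M. For mitochondrially encoded mRNAs, adjusted p = 0.047 and 0.045 with an estimated correlation, in this order. They also rose in 6 of 13 over all genes (12 adjusted over the list alone, median 0.57, adjusted p = 3.7e-18) in G325E, 11 of 13 over all genes (13 adjusted over the list alone, median 0.74, adjusted p = 9.1e-25) in R326H and 11 of 13 over all genes (12 adjusted over the list alone, median 0.80, adjusted p = 9.3e-29) in R351W. For mitochondrially encoded mRNAs, adjusted p = 0.095, 0.056 and 0.047 with an estimated correlation, in this order. WT is low in these mRNAs, with MT-CO1 at 4156 CPM against 12747 in uninfected, 9674 in R534S and 13483 in T532M. MT-RNR2, a mitochondrial rRNA, was at 5746 CPM in WT, 30569 in T532M and 34569.9 in uninfected nuclear-labelled libraries, and reads at several places made up 30.5%, 54.4% and 47.7%. R376C rests there on 1 nuclear-labelled library.

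The ratio changed for 2 genes in G325E (0 without any library but WT cytoplasmic-labelled replicate 2, where it was 3), 22 in T532M, and 0 in R326H, R351W, R376C and R534S by edgeR (561, 474, 4301 and 681 at unadjusted p under 0.05; 15, 4, 1010 and 27 by DESeq2). Without R376C nuclear-labelled replicate 1 or 2 the R376C count was 10361 or 34. In T532M it was 10, 8, 10 and 20 without cytoplasmic-labelled replicates 1 and 2 and nuclear-labelled replicates 1 and 2, and 9, 16, 8 and 9 without those of WT, and the DESeq2 test gave 122 up and 69 down against 20 and 2. The medians over all genes were 0.19 in R376C and -0.12 in T532M, and -0.10 and -0.12 without R376C nuclear-labelled replicate 2, so the sign in R376C rests on that library. Counts in the reduced fit were 188, 185, 113, 34, 485 and 1321, and translation factors fell in 8 of 33 over all genes (17 adjusted over the list alone, median -0.34, adjusted p = 1.8e-15) in G325E and 9 of 33 over all genes (18 adjusted over the list alone, median -0.31, adjusted p = 7.1e-19) in R326H. For translation factors, adjusted p = 0.011 and 0.0050 with an estimated correlation, in this order. They also fell in 18 of 33 over all genes (23 adjusted over the list alone, median -0.47, adjusted p = 4.9e-25) in R534S. For translation factors, adjusted p = 0.0016 with an estimated correlation. In T532M, they fell in 22 of 33 over all genes (25 adjusted over the list alone, median -0.51, adjusted p = 3.5e-24) and proteasome genes in 19 of 36 over all genes (26 adjusted over the list alone, median -0.50, adjusted p = 8.0e-13). For translation factors and proteasome genes, adjusted p = 7.4e-04 and 0.013 with an estimated correlation, in this order. G1/S genes fell in 16 of 32 over all genes (22 adjusted over the list alone, median -0.40, adjusted p = 7.1e-13), while mitochondrially encoded mRNAs rose in 12 of 13 over all genes (12 adjusted over the list alone, median 2.03, adjusted p = 3.3e-39). For G1/S genes and mitochondrially encoded mRNAs, adjusted p = 0.0050 and 0.0064 with an estimated correlation, in this order. The F test among mutants called 1 gene, 0 without T532M cytoplasmic-labelled replicate 1, 9337 and 132 without R376C nuclear-labelled replicates 1 and 2.

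Many genes changed the same way in at least 4 mutants, 218 up and 434 down in the cytoplasmic-labelled libraries. TF (mean -3.03), ASS1 (-2.99), ADM2 (-2.94), INHBE (-2.83) and STC2 (-2.78) fell in all 6, as did PHGDH (-2.64). If the mutants were independent, 0.0687 and 0.413 would be expected, and simulated data with shared WT libraries and no genotype effect gave 0 in 10 draws. In those draws a mean of only 0.417 genes per mutant were called, so a call shared by 4 mutants was hardly possible. They also gave WT no shift of its own, so the 0 cannot tell whether such a shift makes the shared genes. The median covariance of a mutant pair was 0.245 against 0.0736 in the simulation, in which the mutants shared the WT libraries. Shared libraries without a shift thus gave part of that covariance and not all of it. A shift of WT, which the draws lacked, may add to the rest. Nuclear-labelled libraries in the reduced fit gave 875 and 849 (8.67 and 9.16 if independent; covariance 0.169 against 0.0415), and the ratio 29 and 79 (covariance 0.624 against 0.399).

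The genes called for sgDDX3 in the guide set were tested as sets in the transgene set, rises and falls apart. Of the genes that rose in the cytoplasmic-labelled libraries, 134 of 173 (77.5%) had the same sign in no-transgene against uninfected cells, with a median of 0.51 (adjusted p = 2.3e-12; adjusted p = 0.039 with an estimated correlation). For these genes the share was lowest in R351W against WT (95 of 173, 54.9%, adjusted p = 0.055; adjusted p = 0.51 with an estimated correlation). Of 48 such tests, 39 were called, all in the same direction, and 23 kept the call with an estimated correlation. For the ratio 8 of 16 were called, with same-sign shares of 23.5% (R376C, 4 of 17 genes) to 88.7%. Without R376C nuclear-labelled replicate 2 these shares were 35.4% to 89.2%. Over all genes, changes in the 2 sets correlated weakly. Pearson's r was 0.048 to 0.21 in the cytoplasmic-labelled libraries, 0.19 to 0.36 in the nuclear-labelled ones and -0.022 to 0.050 for the ratio. All tests but those against uninfected cells share the WT libraries. The sets were chosen on the guide-set libraries, which share no library with the transgene set. Over the transgene set, 245 of 688 list tests were called and 19 kept the call with an estimated correlation, and in the reduced fit 172 of 456 and 51.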

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

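The tests in this part were chosen after the data were seen. The control for sgDDX3 was sgGal4 in the guide set and uninfected or WT cells in the transgene set. Cytoplasmic-labelled DDX3X was at 245 CPM in sgGal4 and 59.3 with sgDDX3 in the guide set. In the transgene set it was at 290 in uninfected, 315 in WT and 130 in no-transgene cells. Control, depth of knockdown and set cannot be told apart here. The effect of sgDDX3 differed between the guide set and the transgene set by a test of the difference in edgeR, in a fit of all libraries but R376C nuclear-labelled replicate 2. Against no-transgene over uninfected cells it differed for 2332 genes in the cytoplasmic-labelled libraries, 1804 in the nuclear-labelled ones and 915 for the ratio. Against no-transgene over WT cells it differed for 1630, 895 and 451.

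Reads that the comparisons do not use were above both control libraries in several groups. The mean no-feature share was 59.0% in sgDDX3 and 67.8% in sgNUP160 cytoplasmic-labelled libraries (53.6% in sgGal4) and 8.96% in sgNUP160 nuclear-labelled ones (6.99% in sgGal4). It was above both uninfected libraries in all 16 other nuclear-labelled libraries of the transgene set, so the uninfected pair was lowest there. Shares below the controls were not collected. The no-feature share was 5.17% in sgCNOT1 nuclear-labelled libraries, and reads at several places were 30.5% in WT against 47.7% in uninfected nuclear-labelled ones. Reads at several places made up 4.59% and 10.2% of all reads in sgDDX3 cytoplasmic-labelled and nuclear-labelled libraries (4.32% and 9.41% in sgGal4), and lay above both uninfected libraries in 3 cytoplasmic-labelled and 1 nuclear-labelled library of the transgene set. Counts on the opposite strand made up 9.51% in sgDDX3 and 11.4% in sgNUP160 cytoplasmic-labelled libraries (8.87% in sgGal4), and lay above both uninfected libraries in 1 cytoplasmic-labelled and 15 nuclear-labelled libraries.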

How the results depend on the processing

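The fit without R376C nuclear-labelled replicate 2 and the reversed column order were chosen after seeing the data, and the other settings before. Called genes whose number moved by more than 1.5 times are given by setting, and the cause was not tested. With no filter on low counts they were sgDDX3 934 (cytoplasmic-labelled), no transgene against WT 99 (nuclear-labelled) and 3 (ratio), G325E 83 (nuclear-labelled) and 32 (ratio), R326H 28 (ratio), R351W 75 (nuclear-labelled) and 22 (ratio), R376C 3106 (nuclear-labelled) and 2287 (ratio), R534S 32 (ratio), T532M 59 (ratio), among mutants 3104 (nuclear-labelled) and 1592 (ratio). In 1 fit of all libraries they were sgDDX3 1465 (nuclear-labelled), sgCNOT1 3966 (nuclear-labelled) and 446 (ratio), sgNUP160 420 (nuclear-labelled) and 403 (ratio), no transgene against uninfected 1823 (cytoplasmic-labelled) and 1562 (nuclear-labelled) and 29 (ratio), no transgene against WT 220 (cytoplasmic-labelled) and 150 (nuclear-labelled), G325E 183 (cytoplasmic-labelled) and 143 (nuclear-labelled) and 7 (ratio), R326H 191 (cytoplasmic-labelled) and 147 (nuclear-labelled) and 1 (ratio), R351W 184 (cytoplasmic-labelled) and 127 (nuclear-labelled), R376C 29 (cytoplasmic-labelled) and 5777 (nuclear-labelled) and 583 (ratio), R534S 240 (cytoplasmic-labelled) and 170 (nuclear-labelled) and 1 (ratio), T532M 802 (cytoplasmic-labelled) and 1381 (nuclear-labelled), among mutants 228 (cytoplasmic-labelled) and 4767 (nuclear-labelled); DDX3X in R376C nuclear-labelled turned to -0.059 and the SNHG5 ratio in R376C to -0.047. By the DESeq2 test they were sgCNOT1 1601 (ratio), no transgene against uninfected 1644 (nuclear-labelled) and 463 (ratio), no transgene against WT 289 (nuclear-labelled) and 18 (ratio), G325E 256 (nuclear-labelled) and 25 (ratio), R326H 292 (nuclear-labelled) and 15 (ratio), R351W 230 (nuclear-labelled) and 4 (ratio), R376C 1780 (nuclear-labelled) and 1010 (ratio), R534S 360 (nuclear-labelled) and 27 (ratio), T532M 1363 (nuclear-labelled) and 191 (ratio), among mutants 2502 (nuclear-labelled) and 69 (ratio). On unstranded counts they were sgNUP160 1180 (ratio), no transgene against uninfected 23 (ratio), G325E 1 (ratio), among mutants 2 (ratio); GP6 turned to -0.30 in no transgene against uninfected and -0.21 in T532M (cytoplasmic-labelled), and in R376C the ratio of GARS1 to -0.070 and of SNHG5 to -0.25. With DESeq2 size factors, T532M 38 (ratio). Without R376C nuclear-labelled replicate 2 they were no transgene against uninfected 5699 (nuclear-labelled) and 2000 (ratio), no transgene against WT 2623 (nuclear-labelled) and 502 (ratio), G325E 2520 (nuclear-labelled) and 188 (ratio), R326H 2581 (nuclear-labelled) and 185 (ratio), R351W 2195 (nuclear-labelled) and 113 (ratio), R534S 2977 (nuclear-labelled) and 485 (ratio), T532M 5126 (nuclear-labelled) and 1321 (ratio). With an estimated correlation, 19 of 389 list calls and 23 of 39 sgDDX3 set calls remained. That estimate depends on the order of the design columns, because voom weights enter it, and with the columns reversed 22 list calls remained, including all 19.

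With a replicate block the counts were sgDDX3 998 (cytoplasmic-labelled), no transgene against uninfected 1993 (ratio), no transgene against WT 493 (ratio), G325E 216 (ratio), R326H 233 (ratio), R351W 148 (ratio), R376C 4 (nuclear-labelled) and 61 (ratio), R534S 489 (ratio), T532M 1289 (ratio), among mutants 121 (nuclear-labelled) and 208 (ratio), and in R376C the ratios of HAGHL and SNHG5 turned to -1.70 and -1.99. The difference between replicates 1 and 2 correlated above 0.1 between genotypes in 3 of 6 pairs in the guide cytoplasmic-labelled libraries (median 0.10, highest 0.43), so the numbers may pair some of these, where sgDDX3 had 445 without the block. In the guide nuclear-labelled libraries it did so in 0 of 6, and in the transgene set in 4 of 28 and 1 of 28. Between the fractions of a genotype it did so in 0 of 4 pairs in the guide set and 0 of 8 in the transgene set. Negative correlations were not counted, so shared deviations are not excluded. The lowest was -0.54 between fractions in the guide set and -0.42 between genotypes in the transgene cytoplasmic-labelled libraries. For the ratio, the block gives each genotype and replicate number its own coefficient. R376C nuclear-labelled replicate 2 has no cytoplasmic-labelled partner, so it adds nothing to the blocked ratio tests. The blocked ratio counts lie near those of the fit without that library and cannot tell pairing from its loss.

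Leaving out each library in turn, with a lone sample assumed to vary like the other groups, gave ranges of sgDDX3 29 to 133 (cytoplasmic-labelled) and 2752 to 3268 (nuclear-labelled) and 169 to 365 (ratio), sgCNOT1 1360 to 6652 (cytoplasmic-labelled) and 229 to 3901 (ratio), sgNUP160 221 to 1106 (cytoplasmic-labelled) and 955 to 1202 (nuclear-labelled) and 103 to 873 (ratio), no transgene against uninfected 2991 to 5518 (cytoplasmic-labelled) and 123 to 155 (nuclear-labelled) and 0 to 370 (ratio), no transgene against WT 480 to 2565 (cytoplasmic-labelled) and 6 to 20 (nuclear-labelled), G325E 450 to 501 (cytoplasmic-labelled) and 15 to 19 (nuclear-labelled) and 0 to 3 (ratio), R326H 399 to 523 (cytoplasmic-labelled) and 13 to 19 (nuclear-labelled), R351W 406 to 468 (cytoplasmic-labelled) and 14 to 18 (nuclear-labelled), R376C 86 to 95 (cytoplasmic-labelled) and 1 to 12261 (nuclear-labelled) and 0 to 10361 (ratio), R534S 465 to 598 (cytoplasmic-labelled) and 8 to 19 (nuclear-labelled), T532M 1183 to 1634 (cytoplasmic-labelled) and 121 to 292 (nuclear-labelled) and 8 to 20 (ratio), among mutants 291 to 857 (cytoplasmic-labelled) and 26 to 12667 (nuclear-labelled) and 0 to 9337 (ratio). Calls on named genes stayed the same in 6777 of 8124 cases, were lost in 1254, gained in 78 and turned in 15. All 15 lie in R376C, whose nuclear-labelled replicates differ. The log2 fold changes there ranged in the nuclear-labelled libraries over TWF1 -0.92 to 0.90, DDX3X -0.50 to 0.45, NEAT1 -0.44 to 4.18, RPL21 -3.17 to 0.33, RPL38 -2.73 to 0.25, RPL12 -2.81 to 0.24, RPLP1 -2.49 to 0.20, DNAJB1 -1.84 to 0.38 and HSPB1 -2.42 to 0.34. For the ratio they ranged over HAGHL -1.70 to 1.23, PHGDH -0.18 to 1.24, WARS1 -1.03 to 1.10, GARS1 -0.90 to 0.65 and SNHG5 -1.99 to 0.83. SNHG5 was also -0.056 without WT cytoplasmic-labelled replicate 1.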

Other observations

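With sgDDX3, nucleoporins fell in the nuclear-labelled libraries in 19 of 30 over all genes (22 adjusted over the list alone, median -0.31, adjusted p = 1.4e-05) and DEAD-box helicases in 17 of 32 over all genes (19 adjusted over the list alone, median -0.31, adjusted p = 2.9e-05). For nucleoporins and DEAD-box helicases, adjusted p = 0.31 and 0.12 with an estimated correlation, in this order. Falls were also called for mRNA export factors in 12 of 28 over all genes (12 adjusted over the list alone, median -0.26, adjusted p = 0.0011) and mitochondrial ribosomal proteins in 33 of 76 over all genes (36 adjusted over the list alone, median -0.33, adjusted p = 3.9e-08). For mRNA export factors and mitochondrial ribosomal protein genes, adjusted p = 0.16 and 0.10 with an estimated correlation, in this order. CCR4-NOT genes had a ratio higher with sgCNOT1 in 2 of 12 over all genes (4 adjusted over the list alone, median 0.37, adjusted p = 7.6e-04). For CCR4-NOT genes, adjusted p = 0.35 with an estimated correlation. Cytoplasmic mRNA decay genes had a ratio higher with sgNUP160 in 1 of 39 over all genes (3 adjusted over the list alone, median 0.20, adjusted p = 0.0089). For mRNA decay genes, adjusted p = 0.48 with an estimated correlation. Lymphocyte genes and fibroblast and epithelial genes, markers of other cell types, were called in 0 guide-set tests of 9 each, and in 4 of 24 and 1 of 16 transgene-set tests.

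Without a transgene, cholesterol synthesis genes rose against uninfected cells in the cytoplasmic-labelled libraries in 13 of 24 over all genes (14 adjusted over the list alone, median 0.36, adjusted p = 6.1e-05). For cholesterol synthesis genes, adjusted p = 0.041 with an estimated correlation. Without R376C nuclear-labelled replicate 2, erythroid genes fell in R351W nuclear-labelled libraries in 11 of 28 over all genes (13 adjusted over the list alone, median -0.18, adjusted p = 1.8e-04). For erythroid genes, adjusted p = 0.045 with an estimated correlation.

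The tests of the fraction labels and all but 1 of those of the ATF4 pattern were chosen after the results were seen, and the correlation and trend tests of sgNUP160 before. Fraction markers ran against the labels in 50 of 51 libraries. Carry-over of a fraction cannot turn a ratio, and MALAT1 stood at -3.24 in the sgGal4 libraries, so the tables argue against it. Counting on a single strand is argued against as well, since on unstranded counts the nuclear-retained RNAs had a median of -2.73. Exchanged labels could account for the median of -2.65 and stay open, as does a fractionation whose layers were named the other way round, which was not tested. No biological explanation was tested.

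ATF4 list genes lay below WT in every mutant, in R376C by 1 library a fraction. They also fell in no-transgene against uninfected cells (median -1.83), a comparison without WT libraries. That fall cannot come from the WT libraries, and the list fell in no-transgene cells against WT as well. Uninfected cells differ from no-transgene cells by infection and guide too, so for the mutants it cannot decide whether the WT libraries stand apart. In an added comparison WT differed from uninfected cells in 1449 genes in the cytoplasmic-labelled libraries, a count that does not place the ATF4 list. For the mutants, WT libraries that stand apart stay open. Mutant transgenes that are not transcribed are argued against in all but R351W, since DDX3X in the nuclear-labelled libraries stood above its level in uninfected cells, by 0.37 ± 0.05 in R534S and more in the others (in R376C also in the cytoplasmic-labelled library, 0.56 ± 0.11). In the cytoplasmic-labelled libraries R534S missed the edgeR threshold over uninfected cells (0.19 ± 0.09, adjusted p = 0.12), while G325E, R326H and T532M were called higher. Whether the R351W transgene is transcribed cannot be told, because reads up to the level of uninfected cells can come from the gene, so that 0.71 over no-transgene cells decides nothing. A fall in any knockdown is argued against by sgDDX3 against sgCNOT1 (median -0.40, p = 5.8e-07, p = 0.10 with an estimated correlation), although the list fell with sgNUP160 as well (median -0.97). Lower DDX3 function stays open, as the list fell with sgDDX3 in other libraries (median -0.59), a call lost with an estimated correlation (adjusted p = 0.20), and the mutants were not shown to share a cause. In added comparisons of cytoplasmic-labelled libraries, G325E, R326H, R351W and R534S differed from no-transgene cells in 82, 63, 70 and 41 genes. Against WT these mutants had 1078, 917, 991 and 1295. T532M differed from no-transgene cells in 1012 genes and from WT in 2579. R376C, with 1 library, is left aside, and a low count does not show that cells are alike.

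Ribosomal protein and mitochondrially encoded mRNAs had a higher ratio with sgNUP160. Less cytoplasmic RNA in the pellets would tie the effect to the ratio of each gene in uninfected cells, but the rank correlation of 0.0929 meets its bound of 0.1 only within its spread, so this explanation stays open. By the labels the pellets are the nuclear-labelled libraries, in which ACTB was lower (2385 against 2917 CPM in sgGal4) and MT-CO1 higher (12530.4 against 8584). If the labels are exchanged they are the cytoplasmic-labelled ones, with a higher no-feature share (67.8% against 53.6%) and less ACTB (475.8 against 1029.9), GAPDH (190.2 against 325.99) and MT-CO1 (5954 against 15054). Ribosomal protein mRNAs stood above the trend (median residual 0.45, 95% interval 0.31 to 0.50, 67 of 82 above 0), but did so with sgDDX3 (0.17, 0.10 to 0.21, 63 of 82) and sgCNOT1 (0.083, 0.037 to 0.14, 58 of 82) as well. A shift of these mRNAs beyond the trend stays open too, and its cause was not tested.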
